A study of Mus musculus with 17 samples.

How the data were processed

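RNA was sequenced from single whole embryos of C57BL/6J mice, 17 in all. Per the labels' protocols, embryos were dissected, frozen singly while they were genotyped and purified together, RNA was taken with a micro column kit, and libraries were made with a TruSeq RNA kit and sequenced on a NovaSeq instrument. Each embryo is a separate animal, and the labels do not say which embryos shared a litter. The deposited table holds TPM (transcript abundance scaled to a fixed total) for 41709 gene symbols, a unit that the authors' values fit in that each library sums to 1000000. The submitters' processing notes name the genome build GRCm39 (mm39), while the aligner, quantifier and annotation are not given in the sources used here. TPM keeps no read depth, so neither counting intervals nor detection floors are given, and how depth limits each library is unknown.

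Groups were read from the sample titles: Disp1_WT and Disp1_CS_INDEL at E9.5 (4 embryos each), Myo10_WT (4) and Myo10_m1J (5) at E8.5. The tests, the 44 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. TPM was turned into log2(TPM + 1), which understates the fold of genes near or below a TPM of 1. Genes with a TPM of at least 1 in at least 4 libraries of a comparison were tested with limma 3.58.1 in R 4.3.3, using moderated tests with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Each experiment was fitted alone. The difference of the mutant effects was tested in a fit of all 17 libraries, and the E9.5 and E8.5 wild types were compared in a fit of those 8. Levels of the targeted genes and list means were compared with exact two-sided permutation tests, taking double the smaller one-sided p.

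Gene lists for Hedgehog output and machinery, regions and cell types of the embryo, signalling pathways, stress, cilia, filopodia, recycling, extra-embryonic tissue and sex were tested with camera at a preset correlation of 0.01 where at least 3 members were tested. Beside this stand camera with an estimated correlation and fry. The symbols Aldoa, Ddit3 and Ahsp of these lists were not found in the table. Genes were named by rule: the targeted genes and Shh, called genes whose groups do not overlap, the 5 with the smallest p where fewer than 5 passed, the measured Hedgehog targets (not all are printed), the 4 leading members of a called list, the 5 with the smallest p for the difference of the effects among those that passed, and the 3 largest changes each way between the ages. Cnih4, Ifi202b, Stmn2, Cdx4, Msgn1, Hoxc10, Nodal, Lefty1, Afp, Ttr, Cdx2, T and Eno1, members of lists passing over the list alone outside the first 4, and examples from the age comparison were named after their values were seen.

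Alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-of-ratios scaling, haemoglobin and mitochondrial genes left out, no trend, 1 fit of all libraries, a replicate block, the Y-linked or the erythroid mean as a covariate, and each library left out in turn. Protein-coding genes only (without histone and mitochondrial genes), the Disp1 fit without a pair of libraries, the fit without neighbours of the targeted gene, the settings of the Hedgehog target means and of the difference between them, the Disp1 level at E8.5 after scaling, and single lists with each library left out were added after seeing the data. Gene order and biotype came from a RefSeq table of the GRCm38 assembly, in which 30209 symbols matched. Because the authors' build differs, no coordinates are printed.

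The gene tests were tested on simulated data drawn from the real means and spreads with changed genes of known size. In the simulated Disp1 comparison (13336 genes) 70.0% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 were recovered. In the simulated Myo10 comparison (12605 genes) recovery was 38.0% and 88.0%. Each simulation changed 50 genes by each of 0.5, 1, 2 and 3, drawn from genes with a mean above about 5 TPM. In the Disp1 case 190 genes were called, whereas the real comparison called 4. These shares therefore do not carry over to the real data, where fewer changes make the adjustment stricter, or to genes of lower level. Camera recovered a simulated Hedgehog list lowered by 1 in both comparisons, with either correlation, and at the preset correlation it also called 2 unchanged lists in the Disp1 case. Genes were drawn independently, without the correlation within real lists (0.368 for the Hedgehog targets in the Disp1 comparison). The simulation therefore does not measure false list calls in the real data, where wrong groupings of the E9.5 embryos called up to 19 lists. No sample was left out of the main results.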

Results

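Whole mouse embryos were profiled by RNA sequencing, each of the 17 libraries holding the RNA of a single embryo. The first experiment compared 4 wild-type embryos (Disp1_WT) with 4 embryos carrying a CS allele and an INDEL allele of Disp1 (Disp1_CS_INDEL) at E9.5. Disp1 encodes Dispatched, the membrane protein that releases lipid-modified Sonic hedgehog from producing cells. The second experiment compared 4 wild-type embryos (Myo10_WT) with 5 embryos homozygous for the m1J allele of Myo10 (Myo10_m1J) at E8.5. Myo10 encodes myosin X, a motor that travels to the tips of filopodia. The series title places both genes in the loading of morphogen onto cytonemes, the thin signalling filopodia, so both comparisons ask how the transcriptome of the embryo, including the genes that respond to Hedgehog, differs when one of these genes is mutated. Values are TPM, a unit scaled to the same total in every library, which carry no read depth, so the depth of each library is unknown. Between 13103 and 13408 genes reached a TPM of 1 in each E9.5 library, and between 11926 and 12957 in each E8.5 library.

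The targeted transcripts were read first. Myo10 fell from 25.8 ± 6.02 TPM in Myo10_WT (SD, n = 4) to 3.61 ± 0.89 TPM in Myo10_m1J (SD, n = 5), 14.0% of the wild-type mean. The highest mutant embryo (4.35 TPM) lay far below the lowest wild-type embryo (19.9 TPM), and the exact two-sided permutation p of 0.0159 is the smallest that this design can give. Disp1 read 17.5 ± 1.74 TPM in Disp1_WT and 14.3 ± 1.98 TPM in Disp1_CS_INDEL (SD, n = 4 each), a log2 difference of -0.28 with overlapping embryos (exact permutation p = 0.0571). After median-of-ratios scaling the Disp1 difference was -0.29 and its exact permutation p was 0.0286. A transcript level does not read the protein change made by an allele, so the Disp1 value checks the genotype labels only weakly. Myo10 was 28.8 ± 2.32 TPM in Disp1_WT and 29.7 ± 2.58 TPM in Disp1_CS_INDEL (SD, n = 4 each; exact permutation p = 0.60). Shh, the ligand gene, read 23.9 ± 1.97 TPM in Disp1_WT and 20.7 ± 2.25 TPM in Disp1_CS_INDEL (SD, n = 4 each; exact permutation p = 0.0571). At E8.5, Disp1 read 8.84 ± 1.101 TPM in Myo10_WT (n = 4) and 7.04 ± 0.65 TPM in Myo10_m1J (SD, n = 5), a log2 difference of -0.29 with the smallest exact permutation p the design allows (0.0159), but it did not pass over all genes (limma adjusted p = 0.473). The median of all genes in that comparison was -0.16, and after median-of-ratios scaling the Disp1 difference was -0.12 (exact permutation p = 0.0159; limma adjusted p = 0.782). Shh read 6.47 ± 1.56 TPM in Myo10_WT (n = 4) and 5.25 ± 1.09 TPM in Myo10_m1J (SD, n = 5; exact permutation p = 0.206).

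**Figure D1:**
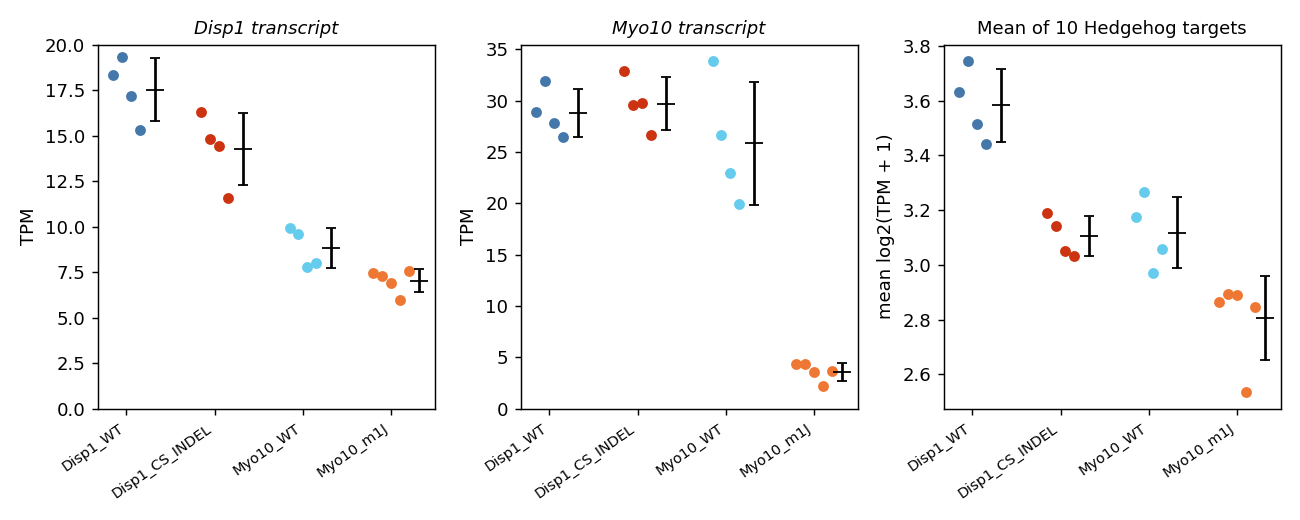
Levels of Disp1 and Myo10 in TPM and the mean log2(TPM + 1) of 10 Hedgehog target genes, with 1 point per embryo in each of the 4 groups and the mean ± SD beside the points. The 5 Myo10_m1J embryos lie at or below 4.35 TPM of Myo10, under all 4 Myo10_WT embryos.

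In Disp1_CS_INDEL embryos the transcripts of Hedgehog target genes were lower. Of the 14 measured targets, 13 had a negative fold change, and 12 of them fell when p-values were adjusted over the list alone. Over all 13294 genes tested, limma called 2 of them lower. These were Nkx2-9, which fell from 22.4 ± 2.48 to 10.8 ± 1.68 TPM (log2 fold change -0.99, SE 0.11, adjusted p = 0.0209), and Nkx2-2, which fell from 4.26 ± 0.44 to 2.11 ± 0.23 TPM (log2 fold change -0.76, SE 0.098, adjusted p = 0.0476). Both encode homeodomain factors of the ventral neural tube, and mutant means were 48.5% and 49.55% of wild type. The general pathway readouts Ptch1 (-0.46, SE 0.088), Hhip (-0.59, SE 0.093) and Gli1 (-0.50, SE 0.14) fell on the log2 scale over the list alone. So did the motor neuron progenitor gene Olig2 (-0.57, SE 0.096), the floor plate and notochord gene Foxa2 (-0.43, SE 0.10) and the forkhead genes of gut-associated mesenchyme Foxf1 (-0.30), Foxf2 (-0.52) and Foxl1 (-0.40). The sclerotome gene Pax1 (-0.28) also passed over the list alone with all embryos, but only without Disp1_WT replicate 4 or Disp1_CS_INDEL replicate 1 when 1 embryo was left out, which gave 11 lower targets in the other cases. Pax9 (-0.12) and Nkx3-2 (0.05) did not pass.

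Averaged over the 14 targets, the mean log2(TPM + 1) was 3.48 ± 0.13 in Disp1_WT and 3.02 ± 0.10 in Disp1_CS_INDEL (SD, n = 4 each). All 4 mutant embryos (2.91 to 3.15) lay below all 4 wild-type embryos (3.31 to 3.60), and the exact two-sided permutation p of 0.0286 is the smallest possible here. In each genotype 3 of 4 embryos carried Y-linked transcripts, and the difference was -0.47 among those embryos and -0.40 between the remaining embryo of each group. The list was called lower by camera with the preset correlation (adjusted p = 4.547e-41), with an estimated correlation (adjusted p = 0.0396), and by fry (adjusted p = 0.0235). The call with an estimated correlation held without Disp1_WT replicate 4 (adjusted p = 0.0296) and ended without any one of the other 7 embryos (adjusted p between 0.0666 and 0.187), although the list median stayed between -0.53 and -0.40. Nkx2-9 kept its call over all genes in 11 of 21 alternative settings (adjusted p between 0.00758 and 1) and Nkx2-2 in 6 of 20 (adjusted p between 0.0208 and 0.486), with a negative fold in each. Leaving out any one of the 8 embryos ended the call of Nkx2-2 (adjusted p between 0.0566 and 0.321), and leaving out any but Disp1_WT replicate 3 or Disp1_CS_INDEL replicate 1 ended that of Nkx2-9 (adjusted p between 0.0566 and 0.182).

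**Figure D2:**
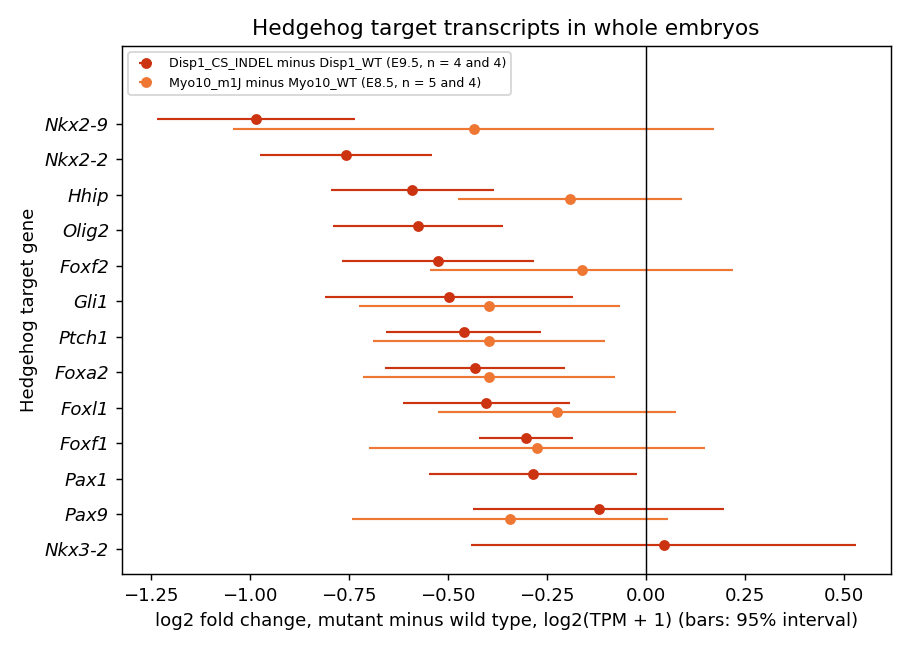
Log2 fold changes of the Hedgehog target genes named in the text on the log2(TPM + 1) scale with 95% intervals from limma, for the Disp1 comparison at E9.5 and the Myo10 comparison at E8.5. In the Disp1 comparison every point but that of Nkx3-2 (0.05) lies below 0, with Nkx2-9 lowest at -0.99. All points of the Myo10 comparison lie below 0.

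Single genes of the dorsal neural tube list rose and single genes of the ventral list fell in Disp1_CS_INDEL. The RNA came from whole embryos, so these changes cannot be placed in the neural tube. Msx1, for instance, is also in the pharyngeal arch list. Of 16 floor plate and ventral neural tube genes, 6 fell when adjusted over the list alone: Nkx2-9, Nkx2-2, Olig2 and Foxa2, which are also in the target list, and the progenitor genes Nkx6-1 (log2 fold change -0.53, SE 0.11) and Nkx6-2 (-0.69, SE 0.17). Of 16 dorsal neural tube genes, 6 rose over the list alone: Pax3 (0.36, SE 0.068), Pax7 (0.37), Zic1 (0.39), Msx1 (0.30), Msx3 (0.37) and Olig3 (0.40). Zic1, for example, read 41.1 ± 4.07 TPM in Disp1_WT and 54.3 ± 6.54 TPM in Disp1_CS_INDEL (SD, n = 4 each). The dorsal count was 3 (Pax3, Msx1 and Zic1) without Disp1_WT replicate 1, Disp1_WT replicate 4 or Disp1_CS_INDEL replicate 1. None of the dorsal genes passed over all genes, the smallest limma adjusted p being 0.339 for Pax3. Pax3 lies on the chromosome of Disp1, though not among the tested genes within 100 places of it. Camera with the preset correlation called both lists (adjusted p = 2.198e-13 for the ventral and 1.112e-10 for the dorsal list). With an estimated correlation neither was called (adjusted p = 0.1765 for each). By fry's mixed test, which asks whether members change in either direction, both passed (adjusted p = 0.00104 and 0.01002), but by its test of change in one direction neither did (adjusted p = 0.305 for each).

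**Figure D3:**
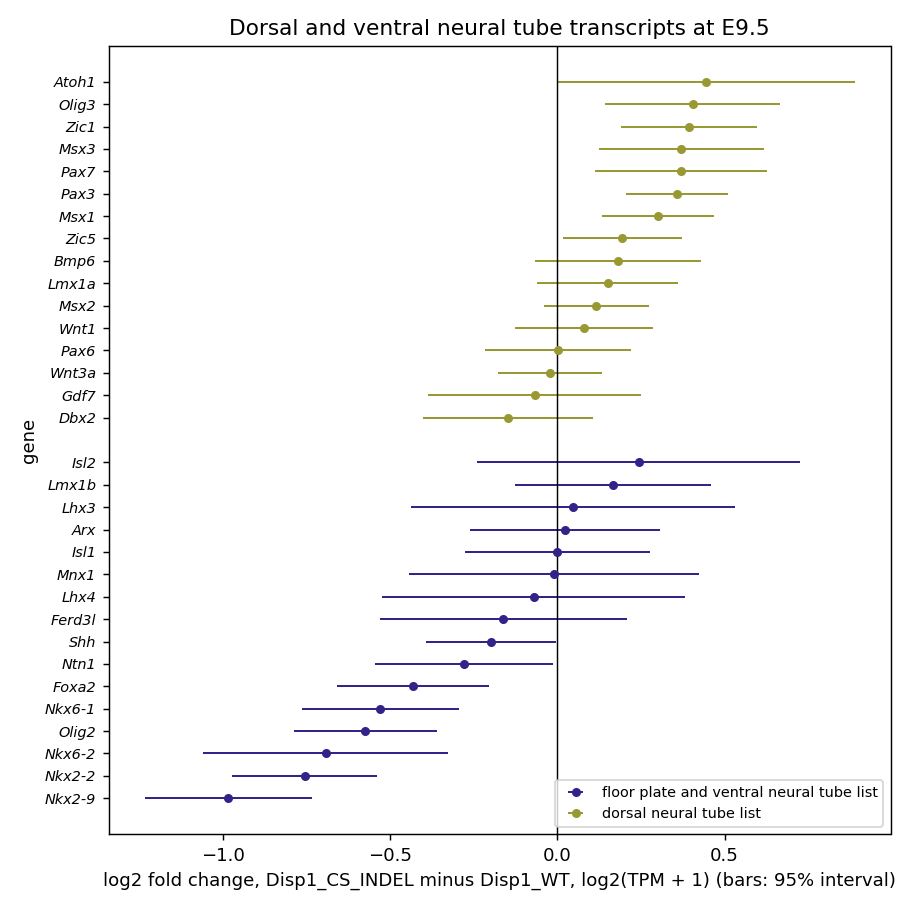
Log2 fold changes, Disp1_CS_INDEL minus Disp1_WT, with 95% intervals from limma for 16 floor plate and ventral neural tube genes and 16 dorsal neural tube genes. Of the ventral genes 12 have a negative fold and of the dorsal genes 13 a positive one.

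The forebrain list split. Nkx2-1, which marks ventral forebrain, fell from 4.00 ± 0.93 to 2.00 ± 0.55 TPM (log2 fold change -0.74, SE 0.16) and Emx2, which marks dorsal forebrain, rose from 9.88 ± 0.25 to 12.8 ± 0.71 TPM (0.34, SE 0.067), both when adjusted over the list alone. The list as a whole was not called in one direction (camera adjusted p = 0.566) and passed fry's mixed test (adjusted p = 0.00140). Emx2 is also in the kidney and intermediate mesoderm list, where it rose over the list alone. That list passed fry's mixed test too (adjusted p = 0.00111), and whole-embryo RNA does not place the rise of Emx2 in the forebrain. In the pharyngeal arch mesenchyme list, Msx1, Prrx1 (0.27) and Alx4 (0.22) rose over the list alone, while Foxd1 (-0.27) was lower without passing. The list was called higher by camera with the preset correlation. Its adjusted p was 0.1765 with an estimated correlation. Leaving out 1 embryo gave 0 genes higher over the list alone without Disp1_WT replicate 3 or 4 or Disp1_CS_INDEL replicate 3. It gave 1 without Disp1_WT replicate 1 or Disp1_CS_INDEL replicate 2, and 2 without Disp1_CS_INDEL replicate 1 or 4. Without Disp1_CS_INDEL replicate 1, Foxd1 also passed as lower. The genes of the Hedgehog machinery itself, among them Smo, Gli2 and Gli3, showed no call (16 members, median 0.06, camera adjusted p = 0.176). Neither did endocytic recycling genes (23 members, median 0.03, camera adjusted p = 0.561) or filopodia and unconventional myosin genes (19 members, median 0.04, camera adjusted p = 0.0604).

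Camera with the preset correlation called 21 of 44 lists in the Disp1 comparison, 6 higher and 15 lower, and only the Hedgehog targets kept the call with an estimated correlation. Visceral yolk sac endoderm had the largest median (-1.07, 11 members). That value followed Disp1_WT replicate 3, in which Apoa1, an apolipoprotein of yolk sac endoderm, read 246 TPM and the decidual prolactin Prl8a2 read 551 TPM. The mutant embryos reached at most 6.28 TPM of Apoa1 and 6.76 TPM of Prl8a2. Without this embryo the yolk sac median was -0.12 (camera adjusted p = 0.0559), and with all embryos its adjusted p with an estimated correlation was 0.485. All 18 cholesterol synthesis genes had a negative fold (median -0.23), among them Sc5d (-0.26, SE 0.18), with a median between -0.38 and -0.09 when 1 embryo was left out (moved most by Disp1_WT replicates 2 and 4 and Disp1_CS_INDEL replicates 2, 3 and 4). So did 15 of 18 hypoxia and glycolysis genes, among them the glucose transporter gene Slc2a1 (-0.17, SE 0.060). No member of either list passed over the list alone, and the adjusted p with an estimated correlation was 0.547 and 0.229. Of the 14 gut endoderm genes 11 had a negative fold, including the keratins Krt8 (-0.31) and Krt18 (-0.24), with an adjusted p of 0.246 with an estimated correlation.

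Besides Nkx2-9 and Nkx2-2, limma called 2 genes in the Disp1 comparison, 1 in each direction. Srp9, a subunit of the signal recognition particle, fell from 47.9 ± 1.42 to 24.1 ± 0.28 TPM (SD, n = 4 each), 50.2% of wild type (log2 fold change -0.97, SE 0.048, adjusted p = 2.117e-05). Ifi204, an interferon-inducible gene, rose from 0.078 ± 0.040 to 1.84 ± 0.20 TPM (log2 fold change 1.40, SE 0.099, adjusted p = 0.000346). Both calls held in every alternative setting that tested the gene, 20 for Srp9 and 14 for Ifi204. The next genes by p did not pass: Lyplal1 (0.47, SE 0.064, adjusted p = 0.0694), Bpnt1 (-0.36, SE 0.058, adjusted p = 0.187) and Psen2 (-0.56, SE 0.097, adjusted p = 0.235), together with the targets Hhip and Olig2 given above. Srp9, Ifi204, Lyplal1, Bpnt1 and Psen2 all lie on the chromosome of Disp1 in the RefSeq gene order, within 46 tested genes of it. Leaving out the tested genes within 100 places of Disp1 removed Srp9 and Ifi204, and the adjusted p of Nkx2-9 and Nkx2-2 then became 0.0619 and 0.0940. In all, 301 genes had an unadjusted p under 0.05, against 664.7 expected by chance alone. With median-of-ratios scaling, limma called 2 genes higher, adding Lyplal1, and 6 lower, adding Hhip, Ptch1 and Olig2.

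In Myo10_m1J embryos Myo10 itself was the one gene past the threshold among 12560 tested (log2 fold change -2.54, SE 0.18, limma adjusted p = 6.681e-05). No gene was called higher. At an unadjusted p under 0.05 there were 854 genes, 43 higher and 811 lower, and the median over all genes was -0.16. Median-of-ratios scaling moved that median to 0.01 and the unadjusted split to 279 higher and 371 lower, with Myo10 still the one call. Structural RNAs (the 7SL, 7SK, RNase MRP and RNase P RNAs) took 33.7% ± 3.49 of the TPM in Myo10_WT (SD, n = 4) and 38.1% ± 4.47 in Myo10_m1J (SD, n = 5; exact permutation p = 0.111). The genes with the next smallest p were the histone gene H2ac13 (-0.40, SE 0.095), the zinc finger gene Zfp771 (-0.39, SE 0.093), the small Cajal body RNA Scarna10 (0.37, SE 0.092), Tmsb15b1 (-1.50, SE 0.38) and Eid3 (-0.63, SE 0.17), all with a limma adjusted p of 0.473. Y-linked transcripts were present in 1 of 4 Myo10_WT and 3 of 5 Myo10_m1J embryos.

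The mean of the Hedgehog targets was also lower in Myo10_m1J. All 10 measured targets had a negative fold change, with a median of -0.32, which minus the median of all genes is -0.16. Examples are Ptch1, at 43.1 ± 4.71 TPM in Myo10_WT and 32.8 ± 5.60 TPM in Myo10_m1J (log2 fold change -0.40, SE 0.13), Gli1 (-0.40, SE 0.15), Foxa2 (-0.40, SE 0.15) and Nkx2-9 (-0.43, SE 0.28). Hhip (-0.19), Foxf1 (-0.28), Foxf2 (-0.16), Foxl1 (-0.22) and Pax9 (-0.34) are further members. With limma no member passed over the list alone or over all genes, and 3 of the 10 (Ptch1, Foxa2 and Gli1) had an unadjusted p under 0.05. The mean log2(TPM + 1) of the 10 targets was 3.12 ± 0.13 in Myo10_WT (n = 4) and 2.81 ± 0.15 in Myo10_m1J (SD, n = 5), a difference of -0.31 with the smallest exact permutation p the design allows (0.0159). The difference was -0.16 after median-of-ratios scaling (exact permutation p = 0.0317) and -0.24 for the same 10 targets over protein-coding genes only (exact permutation p = 0.0159). The protein-coding fit also tested another target, and over those 11, of which 10 were negative, it was -0.20 (exact permutation p = 0.0476). It was -0.40 between 1 and 3 embryos with Y-linked transcripts and -0.24 between 3 and 2 embryos without them. Camera with the preset correlation called the list lower (adjusted p = 0.0225). Its adjusted p was 0.493 with an estimated correlation, and 0.332 by fry. The preset call ended without Myo10_WT replicate 3 (adjusted p = 0.135) or 4 (0.162), or Myo10_m1J replicate 2 (0.0876) or 5 (0.0761), and without Myo10_m1J replicate 1 Ptch1 and Foxa2 passed over the list alone.

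Of the 42 lists tested in the Myo10 comparison, camera with the preset correlation called 13 higher and 3 lower relative to other genes, and none was called with an estimated correlation (smallest adjusted p = 0.362) or by fry (smallest adjusted p = 0.295). The lists called lower were the Hedgehog targets, the Hedgehog machinery and the sclerotome. All 16 machinery genes had a negative fold (median -0.26, or -0.10 after subtracting the median of all genes), among them Gli2 (-0.49, SE 0.18) and Kif7 (-0.37, SE 0.14). All 8 sclerotome genes did too (median -0.35, or -0.19 after subtracting the median of all genes), and Twist1, a mesenchymal transcription factor gene, fell over the list alone from 42.8 ± 5.67 to 33.2 ± 2.14 TPM, while Foxc2 (-0.46, SE 0.16) did not pass. The adjusted p with an estimated correlation was 0.709 for the machinery and 0.450 for the sclerotome. When 1 embryo was left out Twist1 passed only without Myo10_WT replicate 3, where all 8 sclerotome and 5 machinery genes passed over the list alone, and Foxc2 also without Myo10_m1J replicate 1. The preset calls of both lists ended without Myo10_WT replicate 1 or 4 or Myo10_m1J replicate 2 or 5 (adjusted p between 0.0582 and 0.486). Cholesterol synthesis genes (12 of 18 positive, median 0.08), primitive erythroid cell genes (9 of 12 positive, median 0.23) and Y-linked genes (4 of 4 positive, median 1.17) led the lists called higher, each with an adjusted p of 0.362 with an estimated correlation. When 1 embryo was left out the erythroid median ranged from -0.29 without Myo10_m1J replicate 2, -0.10 without Myo10_m1J replicate 4 and 0.03 without Myo10_WT replicate 4 to 0.66 without Myo10_WT replicate 1 and 0.74 without Myo10_m1J replicate 5. The cholesterol median ranged from 0.01 without Myo10_m1J replicate 4 or 5 to 0.14 without Myo10_m1J replicate 1. Filopodia and unconventional myosin genes other than Myo10 (20 members, median -0.21, camera adjusted p = 0.186) and endocytic recycling genes (23 members, median -0.19, camera adjusted p = 0.371) were not called, with 19 of 20 and 23 of 23 folds negative.

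The Disp1 effect at E9.5 and the Myo10 effect at E8.5 were compared with all 17 embryos. Age and library makeup differ between the experiments too, so a difference between the effects cannot be assigned to the mutations alone. Of 13910 genes, limma found a difference between the Disp1 and the Myo10 effect for 3: Myo10 (log2 difference 2.59, adjusted p = 6.618e-06), Ifi204 (1.38) and Srp9 (-0.88). No Hedgehog target was among them. The mean over the 10 targets tested in both comparisons changed by -0.48 in the Disp1 comparison and by -0.31 in the Myo10 comparison, and the difference of -0.17 had an exact permutation p of 0.498 over 8820 rearrangements. The difference was -0.29 (exact permutation p = 0.140) after median-of-ratios scaling over all 17 libraries, which moved the Myo10 value to -0.17 (-0.16 when scaled over the E8.5 libraries alone), and -0.24 (exact permutation p = 0.286) over protein-coding genes. Over all 14 targets it was -0.24 (exact permutation p = 0.261), or -0.35 (0.0571) and -0.32 (0.142) with these scalings, but 4 of them (Nkx2-2, Olig2, Pax1 and Nkx3-2) were too low at E8.5 to be tested there with the values as deposited. The larger value in the Disp1 mutants was thus not shown to differ from that in the Myo10 mutants under any of these scalings. Across the 12017 genes tested in both, the fold changes were unrelated (Pearson r = -0.03, Spearman rho = 0.0018; genes are not independent replicates). Among genes with an unadjusted p under 0.05 in both, 10 shared a direction, against 9.03 expected of independent lists.

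The wild-type embryos of the experiments also differ in age, E9.5 against E8.5, and limma called 9304 of 13397 genes higher and 1364 lower at E9.5. Blood cell genes led the rise. All 13 primitive erythroid genes rose, including the embryonic globin Hbb-y, from 32.3 ± 42.4 TPM in Myo10_WT to 14756 ± 2094 TPM in Disp1_WT (SD, n = 4 each), the adult-type globin Hba-a2 (log2 fold change 6.63, SE 0.51) and the haem synthesis gene Alas2 (4.66, SE 0.33). All 14 genes of differentiating neurons rose as well, for instance Tubb3 (2.88, SE 0.20) and Elavl3 (2.74, SE 0.14), but Stmn2 (0.61, SE 0.15) turned to -0.01 with median-of-ratios scaling and to -0.17 over protein-coding genes. Also higher were 17 of 18 cholesterol synthesis genes, for instance Sqle (1.69, and 0.84 over protein-coding genes) and Idi1 (1.91, and 1.05 over protein-coding genes). Yolk sac endoderm genes fell in 17 of 18 cases, among them Apoa1 (-4.65, SE 1.05) and Ttr (-3.79, SE 0.86), and 8 of 12 tail-bud genes fell, among them Cdx2, from 86.9 ± 42.25 to 16.1 ± 8.74 TPM. Cdx4 (-1.88, SE 0.87) did not pass (limma adjusted p = 0.0658) and passed without Disp1_WT replicate 1, 3 or 4 or Myo10_WT replicate 1 (adjusted p between 0.0322 and 0.0463). Disp1_WT replicate 3 read 3.08 TPM of Cdx2 (other Disp1_WT embryos 19.1 to 21.9) and 0.065 TPM of Cdx4 (others 18.4 to 24.9). This embryo thus adds to the mean fall of these tail-bud genes. Camera with the preset correlation called 8 of 44 lists in the age comparison, 3 higher and 5 lower relative to other genes. By fry 39 were called (smallest adjusted p = 1.058e-06). None of the lists stood apart from other genes by camera with an estimated correlation (smallest adjusted p = 0.962).

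The age comparison crosses the experiments, and the libraries of the experiments differ in makeup, so age and experiment cannot be told apart. The 5 structural RNAs took 29.7% to 44.5% of the TPM in every E8.5 library and at most 0.0132% in any E9.5 library. Histone genes took 8.43% ± 0.45 in Myo10_WT and 0.44% ± 0.0075 in Disp1_WT (SD, n = 4 each). The labels name the same library kit for all libraries, so they do not account for these differences, whose cause was not tested. The largest falls were those of Rpph1 (-12.83, SE 0.18), Rn7s2 (-12.63) and Rn7s1 (-12.47), and the largest rise was that of Eno1b (10.18, SE 0.20), whose near-identical parent gene Eno1 read 1122 ± 30.1 TPM at E8.5 and 1005 ± 68.3 TPM at E9.5. Eno1b and Eno1, and likewise Hba-a1 and Hba-a2, can exchange reads, so single values of these genes are uncertain. The median over all genes was 0.62 as deposited. It was 0.00026 after median-of-ratios scaling, with 4829 genes higher and 4901 lower, and -0.16 over protein-coding genes alone, with 3406 higher and 5874 lower. Over protein-coding genes, 13 of 13 erythroid, 12 of 14 neuronal and 16 of 18 cholesterol synthesis genes were higher, and 18 of 18 yolk sac and 11 of 12 tail-bud genes were lower.

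**Figure D4:**
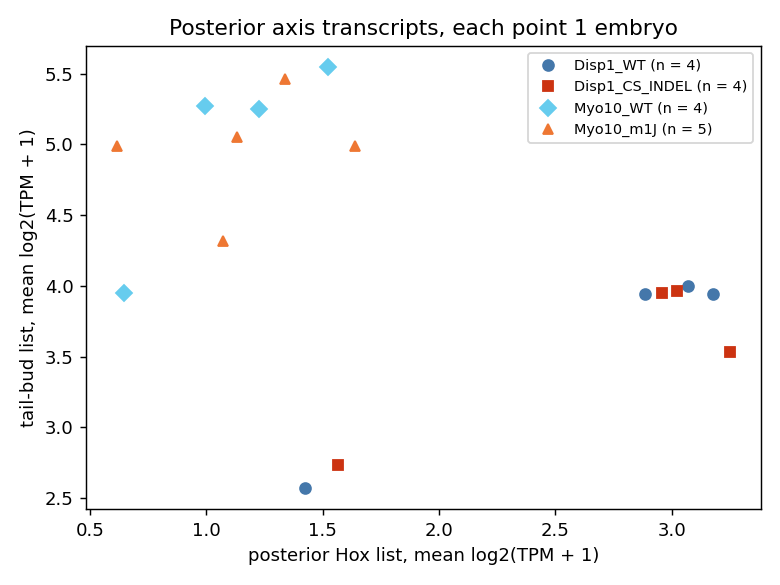
Mean log2(TPM + 1) of the posterior Hox list against that of the tail-bud list, 1 point per embryo, in 4 groups. Disp1_WT replicate 3 (1.43 and 2.57) and Disp1_CS_INDEL replicate 1 (1.57 and 2.73) lie apart from the other 6 E9.5 embryos, which have posterior Hox means of 2.89 to 3.25 and tail-bud means of 3.54 to 4.00.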

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

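The tests in this part were chosen after the patterns were seen, except those of other groupings of the embryos, of the difference between the effects and of the lists with camera. For the test of further genes near Disp1 the prediction was written before its value was seen. Of 234 groups of values checked for a stray embryo, 15 held one, against 11.7 expected by chance at about 1 in 20.

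Genes close to Disp1 were frequent among the genes that separated the Disp1 genotypes. Of 19 genes with an unadjusted p under 0.001, 6 lay within 100 tested genes of Disp1 (Srp9, Ifi204, Psen2, Cnih4, Bpnt1 and Lyplal1) against 0.232 expected, a Fisher's exact p of 7.08e-08. Sex signal as the source is argued against, since 3 of 4 embryos carried Y-linked transcripts in each genotype. After median-of-ratios scaling 5 of the 6 kept a p under 0.001, which by the prediction left scaling undecided. A scaling factor moves all genes of a library the same way. Of these 6 genes 3 were higher and 3 lower in the mutants, which argues against scaling as their common source. A candidate explanation is a stretch of chromosome carried along with the edited Disp1 alleles: with the 19 genes set aside, 15 of the other 152 genes in this window had a p under 0.05 against 3.17 expected (Fisher's exact p = 6.47e-07, taking genes as independent), and Ifi202b, a relative of Ifi204, read 0.138 to 0.702 TPM in Disp1_CS_INDEL and at most 0.0470 TPM in Disp1_WT. Such a stretch would have to differ in sequence from the wild type, as one from another strain would. The labels give C57BL/6J for every embryo and do not say where the alleles were made. An effect of Disp1 or of its edit on neighbouring genes would give the same counts, so both explanations stay open. Whether expression or only the matching of reads differs is open too.

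The lower Hedgehog target mean in Myo10_m1J (-0.31) was weighed against the makeup of the libraries. For the same 10 targets it was -0.16 with median-of-ratios scaling, which brought the all-gene median to 0.01 (exact permutation p = 0.0317), and -0.24 with protein-coding genes only, where that median stayed at -0.06 (0.0159), so the makeup is argued against as the whole source but may account for part of it (-0.19 with the structural RNA share as a covariate). With the Y-linked mean as a covariate the difference was -0.31 (permutation p = 0.0317), which argues against unequal sex signal. With the erythroid mean, a rough guide to age within E8.5, it was -0.31 but the permutation p rose to 0.0635, so age stays open. The biological explanation, lower Hedgehog output, also stays open: against other genes the list did not stand apart (camera adjusted p = 0.493 with an estimated correlation).

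Posterior transcripts were low in 2 E9.5 embryos, 1 of each genotype. In Disp1_WT replicate 3 the tail-bud mean was 2.57 and the posterior Hox mean 1.43, far below the other wild types, with T at 1.32 TPM, Cdx2 at 3.08 TPM and Cdx4 at 0.06502 TPM. In Disp1_CS_INDEL replicate 1 these means were 2.73 and 1.57. Their posterior Hox means lie in the E8.5 range (0.616 to 1.64), as a younger age would give. An age near E8.5 is argued against because the higher of their tail-bud means (2.73) lay below every E8.5 embryo (3.95 to 5.55). Their haemoglobin shares (4.85% and 3.78%) also lay far above those at E8.5 (at most 0.539%). Both tail-bud means lay below the other E9.5 embryos (3.54 to 4.00), not nearer the E8.5 values. The E8.5 libraries come from another experiment with another makeup, so a smaller delay is not excluded. A failed library is argued against by gene counts of at least 13338 at a TPM of 1. Missing caudal tissue may be the source but is not settled, since the lower of their anterior Hox means (3.99) lay just under the range of the other embryos (4.01 to 4.30); as both genotypes are affected, a genotype effect was not tested.

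Other values that stood apart from the rest of their group are given without weighing. The effects of Ifi204 (1.38) and Srp9 (-0.88) differed between the experiments by limma's test of the difference, as did that of Myo10 itself (2.59). In Disp1_WT replicate 3, Afp read 210 TPM (others 21.9 to 31.1) and Stmn2 13.9 TPM (others 8.75 to 9.17). In Disp1_WT replicate 4, structural RNAs took 0.0112% (others at most 0.00558%) and Rn7s2 read 32.5 TPM (others at most 11.5). In Disp1_CS_INDEL, Nkx6-1 was highest in replicate 1 at 22.9 TPM (others 17.03 to 17.27), Emx2 lowest in replicate 3 at 11.8 TPM (others 13.1 to 13.2) and Krt18 lowest in replicate 2 at 136.6 TPM (others 182.2 to 187.6). In Myo10_WT replicate 1 haemoglobin genes took 0.204% (others at most 0.0579%). In Myo10_m1J, histone genes took 7.01% in replicate 2 (others 7.99% to 8.35%) and Gli1 read 4.80 TPM in replicate 4 (others 7.25 to 7.77).

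Other groupings of the same embryos were fitted to see whether chance could give as many calls. In the Disp1 comparison 1 of 35 splits, the real one, gave 4 genes (highest other 2), and 1 of 35 gave 21 lists (highest other 19). That share is the smallest that 35 splits can give, so it argues against chance for the gene count without excluding it. For the lists it says less, because a wrong grouping called nearly as many. The age comparison gave 10668 genes in 1 of 35 splits (highest other 6), but its groups also differ in library makeup, so this count does not speak for age. The difference of the effects gave 3 genes in 2 of 100 rearrangements (highest other 3). Another rearrangement thus gave as many, and chance is made unlikely but not excluded for that count. In the Myo10 comparison 11 of 100 splits gave at least the 1 gene of the real split and 44 of 100 gave at least its 16 lists (highest other 28), so chance is not excluded for these counts. That gene is the mutated Myo10, and a bare count does not test its fall. All mutant embryos (at most 4.35 TPM of Myo10) lay below all wild types (at least 19.9 TPM). Among the other splits of these E8.5 embryos the highest count was 246 genes, and what sets those groups apart was not tested.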

How the results depend on the processing

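The fits over protein-coding genes, without 2 libraries and without neighbouring genes, and all settings of the Hedgehog target mean, were chosen after seeing the data; the others were planned. The Disp1 genes higher (1) became 0 with a mean TPM of at least 5, 0 without the 2 libraries lowest in posterior Hox, 0 without neighbours of Disp1 and 2 with median-of-ratios scaling. The Disp1 genes lower (3) became 1 without a filter, 1 with all libraries in 1 fit, 0 without neighbours and 6 with median-of-ratios scaling. Each 0 for genes higher is Ifi204 leaving by construction: it reads at most 2.085 TPM, lies near Disp1, and fails the filter when a mutant embryo is missing. Without neighbours Srp9 is removed too, and Nkx2-9 and Nkx2-2 keep their folds but not their calls; for the other changes the cause was not tested. The Myo10 genes lower (1) became 2 without a filter, 2 without haemoglobin and mitochondrial genes, and 0 without neighbours, which removes Myo10 itself. The difference of the effects rose from 3 to 8 genes without a filter. Lists called fell from 21 to 1 (Disp1) and from 16 to 0 (Myo10) with an estimated correlation, and likewise to 1 and 0 with fry. The Myo10 lists also numbered 8 without a filter, 6 with median-of-ratios scaling and 10 with the Y-linked covariate. The Disp1 level was -0.29 with median-of-ratios scaling and passed there.

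Leaving out 1 library at a time gave 0 to 1 Disp1 genes higher (0 without any one mutant embryo) and 1 to 2 lower (1 without Disp1_WT replicate 1 or 2 or Disp1_CS_INDEL replicate 2, 3 or 4), 0 to 1 Myo10 genes higher and 1 to 2 lower (1 and 2 without Myo10_WT replicate 4), 2 to 4 genes for the difference, 9591 to 10719 age genes, 16 to 23 Disp1 lists and 9 to 16 Myo10 lists (9 without Myo10_WT replicate 3). The Disp1 level ranged from -0.35 to -0.19 and the Myo10 level from -2.65 to -2.41. The Hedgehog target mean ranged from -0.51 to -0.41 (Disp1) and from -0.36 to -0.24 (Myo10). In the Disp1 comparison Nkx3-2 turned negative without the 2 libraries (-0.0498) and ranged from -0.0985 to 0.211 with 1 library left out (negative without Disp1_WT replicate 4 or Disp1_CS_INDEL replicate 1 or 3). Myo10 turned negative without the 2 libraries (-0.0191) and ranged from -0.00473 to 0.0942 (negative without Disp1_CS_INDEL replicate 1); neither was called. In the age comparison Stmn2 turned to -0.0105 with median-of-ratios scaling and -0.174 over protein-coding genes.

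With the replicate block the Disp1 genes lower were 1, the Myo10 genes higher 1 and the Myo10 genes lower 45. The numbers share no stated litter or day, and same-numbered embryos correlated by 0.0915, 0.0767, -0.241 and 0.348 (Disp1) and -0.0543, 0.154, -0.287 and 0.463 (Myo10), so they do not pair the embryos. Depth is unknown from TPM and its limits could not be set.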

Other observations

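The E8.5 embryos of both genotypes varied widely in several genes, picked after their values were seen. Nodal, a left-side signalling gene, ranged from 0.192 to 13.57 TPM in Myo10_WT and from 0.257 to 12.11 TPM in Myo10_m1J, and its antagonist Lefty1 from 0 to 12.33 and from 0 to 7.95 TPM. Hbb-y ranged from 6.42 to 95.5 TPM in Myo10_WT and from 1.02 to 464.7 TPM in Myo10_m1J, and the atrial gene Nppa from 0.0627 to 2.56 and from 0.0621 to 3.90 TPM. Prl8a2, a decidual transcript, reached 146.5 TPM in 1 Myo10_m1J embryo and at most 2.83 TPM in Myo10_WT.

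In the 2 E9.5 embryos low in posterior transcripts, several caudal genes, also picked after their values were seen, were near 0. Hoxc10 read 0.134 TPM in Disp1_WT replicate 3 and 1.46 TPM in Disp1_CS_INDEL replicate 1, against group maxima of 50.5 and 54.6 TPM. Cdx4 read 0.0650 and 0.243 TPM in these embryos, and Msgn1, a gene of presomitic mesoderm, 0.104 and 0 TPM. Hoxc8, which is expressed further forward, ranged only from 12.24 to 15.9 TPM over the Disp1_WT embryos and from 12.24 to 13.6 TPM over the Disp1_CS_INDEL embryos.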
